A study of Homo sapiens with 12 samples.

How the data were processed

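RNA was measured in 12 libraries of U2OS cells, a human osteosarcoma line, in 4 groups of 3: cells given the solvent DMSO, 10 µM TH10785, 10 µM PNKP1i, or both compounds at 10 µM each, all for 24 h. Per the labels' protocols, RNA was extracted with TRIzol, libraries were built with a NEBNext Ultra RNA kit and sequenced as paired reads of 150 bp on an Illumina NovaSeq. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.6.1, DESeq2 1.30.1 and the builds GRCh38 and hg38, without saying which annotation was counted or whether strand was used. Reads from a gene and from a gene overlapping it on the opposite strand may therefore be mixed in these counts. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

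The first table deposited by the authors holds raw read counts for 58735 genes. Its Ensembl identifiers are those of GENCODE release 29, which was used here for gene types, positions (GRCh38), transcript length and GC content. The second table deposited by the authors holds a normalized signal for 35754 genes. Each of its values is the raw count divided by 1 size factor per library. The 22981 genes found only in the raw table had a summed count of 0 over the 12 libraries, and a further 955 genes were at 0 throughout the normalized table. Depth ran from 16225339 to 21546369 counts per library. No replicate pair held identical counts, and the chi-square per gene between replicates of a group ran from 3.12 to 39.4, so every library was counted as 1 sample.

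The raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr over the 4 groups (minimum count 10, minimum total 15), which left 17290 genes. Libraries were scaled by TMM, and a model with a mean for each group over the 12 libraries was fitted by robust quasi-likelihood. Quasi-likelihood F tests, two-sided, compared TH10785 with DMSO, PNKP1i with DMSO, the combination with DMSO and with each single agent, and tested the interaction (combination minus TH10785 minus PNKP1i plus DMSO, on the log2 scale). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE). Expression levels are CPM (counts over a common library total, scaled by TMM), as mean ± SD over 3 libraries. The biological coefficient of variation was 15.4%. The study's own statistical model is not given in the sources used here.

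Gene lists for 38 pathways, complexes and marker sets were fixed before the data were examined, as were all choices given here unless stated otherwise. Of the 1098 list entries, 1096 matched a gene of the table, and 37 lists had at least 5 tested members. Lists were tested with camera (limma 3.58.1), a test of whether the members' changes rank differently from those of other genes, on log2 CPM with a prior count of 2 and the correlation between members preset at 0.01. Camera with an estimated correlation and fry were run as alternatives. For each list the members past the gene test were counted, once adjusted over all genes and once adjusted over the list alone.

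The genes named were set by a rule. It takes OGG1 in every comparison; for each comparison with DMSO the 8 genes with the largest rise and the 8 with the largest fall, and for the other comparisons the 4 highest and 4 lowest, among called genes with a symbol, a mean log2 CPM of at least 1 and groups that do not overlap (no such condition for the interaction); up to 4 members with the smallest p from each list that was shifted or had at least 3 called members; and CDKN1A, MDM2, HMOX1 and CYP1A1 against DMSO. For the combination this rule takes more genes than are printed, so the text gives examples from it. List members named as exceptions to the direction of their list, and coordinates, fall outside the rule and were chosen after the values were seen. Some genes that the rule takes are not reported here.

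The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited normalized values plus 1, no filter beyond 1 count over the 12 libraries, a stricter filter (CPM of 1 in 3 libraries and a summed count of 120), a fit of only the groups compared, a test against a fold change of 1.2 (glmTreat), the replicate number as a block, and each library left out in turn. After the libraries were seen to differ in their trend with GC content, per-library offsets from splines of GC content and transcript length (5 degrees of freedom) were added as a further alternative. GC content and length were available for 17282 of the 17290 tested genes.

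The gene tests were tested on simulated data, with counts drawn for the 17290 genes with 200 changed genes. For TH10785 against DMSO, 29.9% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For PNKP1i against DMSO the shares were 38.8%, 76.1% and 100%, for the combination against DMSO 34.3%, 80.6% and 100%, and for the interaction 9%, 34.3% and 93.9%. False calls made up 2.1% of the calls for the combination against DMSO and 9.3% for TH10785 against DMSO. These simulations held 200 changed genes and no GC trend. In the data 7093 genes were called for the combination against DMSO and 5289 for the interaction, so the shares do not carry over to those tests. In counts simulated for the combination against DMSO with a GC trend of 0.4 log2 units per SD of GC content, 4100 false calls arose without the offsets and 16 with them. Comparisons that share the DMSO libraries were set beside 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.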

Results

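Gene expression was measured by RNA sequencing in U2OS cells, a line derived from a human osteosarcoma, after 24 h with DMSO, with 10 µM TH10785, with 10 µM PNKP1i, or with both. TH10785 is a small-molecule activator of OGG1, the DNA glycosylase that removes oxidised guanine in base excision repair. The sample labels write TH10785 and the series record TH10587, and the labels' name is used here. PNKP1i is an inhibitor whose structure is not given in the sources used here. Each of the 4 groups had 3 libraries. Total counts were 16547236, 16945507 and 19242525 in the DMSO libraries, 16225339, 19540768 and 20596877 with TH10785, 19082411, 18872657 and 21546369 with PNKP1i, and 18187651, 19014550 and 19603594 with both (replicates 1 to 3). The comparisons ask what each compound does to the transcriptome alone, and whether the pair does something that the sum of the single effects does not give.

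The groups differed mainly by the combination. Against DMSO, 97 of 17290 genes changed with TH10785 and 34 with PNKP1i, while 7093 (41%) changed with both, at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. On the first principal component, which held 50.4% of the variance, the 3 combination libraries lay between 47.7 and 88.6 and the other 9 libraries below 0. Replicate 3 of TH10785 stood apart from its partners, at -54.5 on the first component and -45.9 on the second, where its partners were at 6.6 and -0.8.

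**Figure D1:**
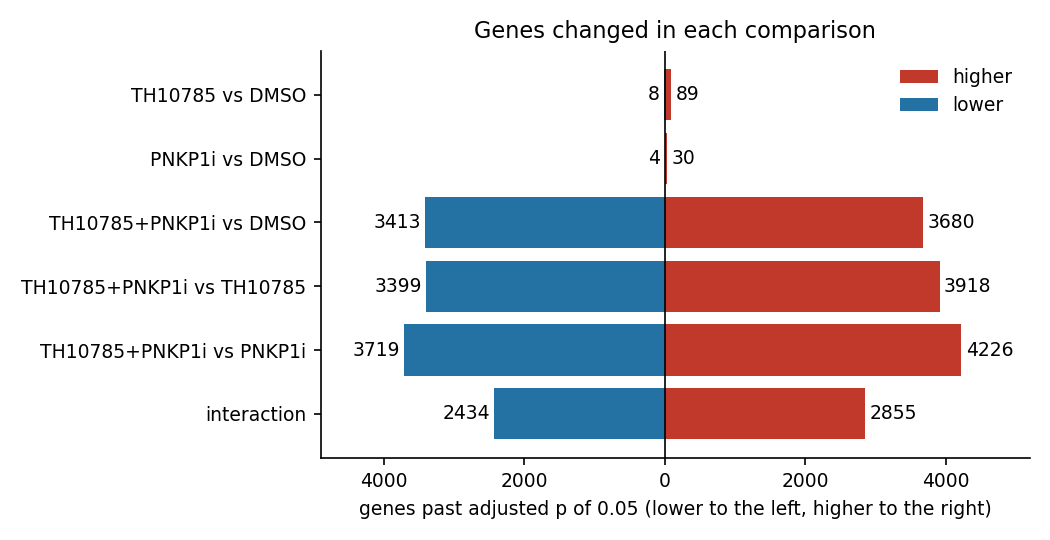
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons (edgeR quasi-likelihood test, 17290 genes tested), with genes that rose to the right and genes that fell to the left. TH10785 changed 89 and 8 genes and PNKP1i 30 and 4, against 3680 and 3413 with the combination.

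With TH10785 alone, cells raised the genes that make cholesterol. Of the 24 measured members of the cholesterol synthesis list, 21 rose and 0 fell (22 rose when adjusted over the list alone), with a median log2 fold change of 1.23. FDFT1 (ENSG00000079459, chromosome 8, 11795573 to 11839309), the squalene synthase, rose 3.18-fold, from 200 ± 23 to 636 ± 86 CPM (SD, n = 3; log2 1.67, SE 0.14, adjusted p = 1.14e-05). HMGCS1, which makes HMG-CoA, rose from 53.3 ± 6.3 to 171 ± 40 CPM (log2 1.68, SE 0.18). INSIG1, a sterol-regulated membrane protein that retains SREBP in the endoplasmic reticulum, rose by 1.68 on the log2 scale and MVD by 1.59. In each of the 3 TH10785 libraries the list median lay 1.23 to 1.29 above the DMSO mean, against -0.05 to 0.09 in the PNKP1i libraries.

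Fatty acid genes moved with them. In the fatty acid synthesis and lipid storage list 7 of 21 members rose and 0 fell (12 rose when adjusted over the list alone), with a median of 0.49. SCD, which desaturates fatty acids, rose from 441 ± 29 to 1030 ± 46 CPM (log2 1.22, SE 0.12, adjusted p = 1.86e-05), FASN, the fatty acid synthase, by 1.24, PNPLA3 by 1.26 and ACSS2, which activates acetate, by 0.93. Both lists were shifted up by camera (adjusted p = 7.59e-41 and 9.1e-12) and kept their calls (adjusted p = 0.00103 for each) with an estimated correlation.

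Outside these lists, rises were ranked among called genes with a mean log2 CPM of at least 1 and groups that did not overlap. The largest were in PTPRR, a receptor tyrosine phosphatase (log2 2.18, SE 0.39, adjusted p = 0.0107), the non-coding LINC02615 (1.90), ALDOC, an aldolase of glycolysis (1.85), ALPL, an alkaline phosphatase (1.82), PTP4A3 (1.76) and KISS1 (1.75, SE 0.16, adjusted p = 1.86e-05). Among the 8 genes that fell were BHLHE41, a circadian repressor (-1.17, SE 0.24, adjusted p = 0.0357), SEMA3E (-0.94), SFMBT2 (-0.92), SBK1 (-0.91), KRT75 (-0.88), ZNF703 (-0.85) and MIDN (-0.55). OGG1 stood at 52 ± 8.4 CPM with TH10785 and 51.8 ± 4.6 with DMSO (log2 0.00, SE 0.13, adjusted p = 0.991). CDKN1A, a p53 target that blocks the cell cycle (log2 0.40, adjusted p = 0.182), MDM2 (0.10, adjusted p = 0.863), HMOX1 (0.60, adjusted p = 0.111) and CYP1A1 (0.32, adjusted p = 0.782) did not pass the test. None of the 36 members of the base excision and single-strand break repair list passed, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.309).

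Camera also called 8 further lists for TH10785, none of which held with an estimated correlation. Cytosolic ribosomal proteins had a median of 0.45, with 0 of 73 members past the test over all genes and 52 when adjusted over the list alone (camera adjusted p = 1.16e-24, and adjusted p = 0.508 with an estimated correlation). The ATF4 integrated stress response list had a median of 0.28, with 0 of 36 members past the test and 6 adjusted over the list alone (adjusted p = 6.46e-08, and 0.494 with an estimated correlation). Medians were 0.29 for nuclear-encoded oxidative phosphorylation (0.656 as adjusted p with an estimated correlation), 0.17 for replication-dependent histones and 0.17 for glycolysis (both 0.656), -0.20 for G2/M genes (0.672), -0.24 for fatty acid oxidation (0.249) and -0.38 for the mitochondrially encoded genes (0.656). The calls of the histone, glycolysis and G2/M lists also ended without TH10785 replicate 3, at adjusted p = 0.0524, 0.511 and 0.25, and that of the histones with GC and length offsets, at 0.511.

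At an unadjusted p under 0.05, 2445 genes passed for TH10785, and in 3403 genes (19.7%, where chance gives 10%) the 3 TH10785 libraries did not overlap the 3 DMSO libraries. The count of 97 fell to 44 without DMSO replicate 2, 47 without DMSO replicate 3 and 53 without TH10785 replicate 2. It was 178 without combination replicate 1, 338 with DESeq2, 513 with no low-count filter, 56 in the test against a fold change of 1.2 and 306 with GC and length offsets, of which 65.7% were rises against 91.8% of the 97. Each cholesterol and fatty acid gene named above kept its call in each of the 23 settings (FDFT1, HMGCS1, INSIG1, MVD, SCD, FASN, PNPLA3 and ACSS2). Of the falls named above only ZNF703 did. PTPRR was called in 21 settings and LINC02615 in 19, with calls ending for PTPRR with limma-voom (adjusted p = 0.051) and without DMSO replicate 3 (0.119) and for LINC02615 without DMSO replicates 1, 2 and 3 (0.054, 0.0966 and 0.0704) or TH10785 replicate 2 (0.0705).

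With PNKP1i alone, cells raised targets of ATF4, the transcription factor of the integrated stress response, and of NRF2, the regulator of antioxidant genes. In the ATF4 integrated stress response list 9 of 36 members rose and 0 fell (27 rose when adjusted over the list alone), with a median log2 fold change of 0.66. PCK2 (ENSG00000100889, chromosome 14, 24094053 to 24110598), the mitochondrial PEP carboxykinase, rose 2.29-fold, from 94.5 ± 5.1 to 217 ± 28 CPM (SD, n = 3; log2 1.2, SE 0.14, adjusted p = 0.00169). ASNS, the asparagine synthetase, rose from 3.84 ± 0.93 to 10.8 ± 1.8 CPM (log2 1.49, SE 0.21, adjusted p = 0.0043), CHAC1, which degrades glutathione, by 1.24, DDIT4, an inhibitor of mTORC1, by 0.88, and PSAT1, of serine synthesis, by 0.82.

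In the NRF2 antioxidant response list 4 of 34 members rose and 0 fell (19 rose when adjusted over the list alone), with a median of 0.48. NQO1, a quinone reductase, rose from 189 ± 33 to 357 ± 5.5 CPM (log2 0.91, SE 0.15, adjusted p = 0.0128), HMOX1, the haem oxygenase, from 42.6 ± 1.5 to 82.8 ± 6.8 CPM (log2 0.96, adjusted p = 0.0173), FTL, the ferritin light chain, by 0.85, and TRIM16L by 0.98. TRIM16L has a close paralog and FTL has many pseudogenes, so their counts are uncertain. Camera shifted both lists up (adjusted p = 4.69e-29 for ATF4 and 1e-15 for NRF2). With an estimated correlation the NRF2 list kept its call (adjusted p = 0.0144) and the ATF4 list did not (adjusted p = 0.052).

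The other genes that rose with PNKP1i were ranked among called genes with a mean log2 CPM of at least 1 and groups that did not overlap. The largest changes were in SLC7A3, a cationic amino acid transporter (log2 1.68, SE 0.26, adjusted p = 0.0089), DHRS3, which reduces retinal (1.5), INHBE (1.35), ASS1, of arginine synthesis (1.14), and RN7SL2, a signal recognition particle RNA with near-identical copies (1.14, uncertain for that reason). Among the 4 genes that fell were ABCG1, a cholesterol exporter, from 17.9 ± 1 to 6.96 ± 2.1 CPM (log2 -1.36, SE 0.19, adjusted p = 0.0043), CYP24A1, which inactivates vitamin D (-0.81), and MANF (-0.71). OGG1 was at 56.2 ± 1.8 CPM (log2 0.12, SE 0.13, adjusted p = 0.739). CDKN1A (-0.12, adjusted p = 0.737), MDM2 (-0.36, adjusted p = 0.487) and CYP1A1 (0.32, adjusted p = 0.793) did not pass. None of the 24 cholesterol synthesis genes passed (median -0.03, camera adjusted p = 0.852), nor any of the 36 of base excision and single-strand break repair (median 0.09, camera adjusted p = 0.116).

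Camera called 5 more lists up for PNKP1i, with 0 members past the gene test in each and no call left with an estimated correlation. They were cytosolic ribosomal proteins (median 0.31, adjusted p = 0.727 with an estimated correlation), NF-kB and inflammatory genes (0.33, with 4 of 22 rising when adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), nuclear-encoded oxidative phosphorylation (0.17, adjusted p = 0.82), antioxidant enzymes and nucleotide pool sanitation (0.13, 2 rising when adjusted over the list alone, adjusted p = 0.727) and lysosome and autophagy (0.06, 2 rising when adjusted over the list alone, adjusted p = 0.727). The last 3 calls also ended with GC and length offsets (adjusted p = 0.122, 0.0836 and 0.122), and for oxidative phosphorylation and antioxidant enzymes without DMSO replicate 3 (0.202 and 0.0733) and for lysosome and autophagy without DMSO replicate 1 (0.286) or PNKP1i replicate 2 (0.101).

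At an unadjusted p under 0.05, 1957 genes passed for PNKP1i, and 4470 (25.9%, where chance gives 10%) had groups that did not overlap. The count of 34 was 7 without PNKP1i replicate 1, 9 without PNKP1i replicate 3, 22, 13 and 8 without DMSO replicates 1, 2 and 3, 22 and 301 without TH10785 replicates 2 and 3, 67 without combination replicate 1. It was 115 with DESeq2, 189 with no low-count filter, 91 with GC and length offsets, 12 in the test against a fold change of 1.2 and 1144 in a fit of only the 6 libraries compared. Those 1144 were 577 rises and 567 falls and held all 34. PCK2, CHAC1, INHBE, ASS1, DDIT4 and PSAT1 were called in each of the 23 settings, ASNS in 22, SLC7A3 and ABCG1 in 21, TRIM16L in 20, DHRS3 in 19, NQO1 in 18, MANF in 17, HMOX1 in 16, RN7SL2 and CYP24A1 in 14 and FTL in 13.

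**Figure D2:**
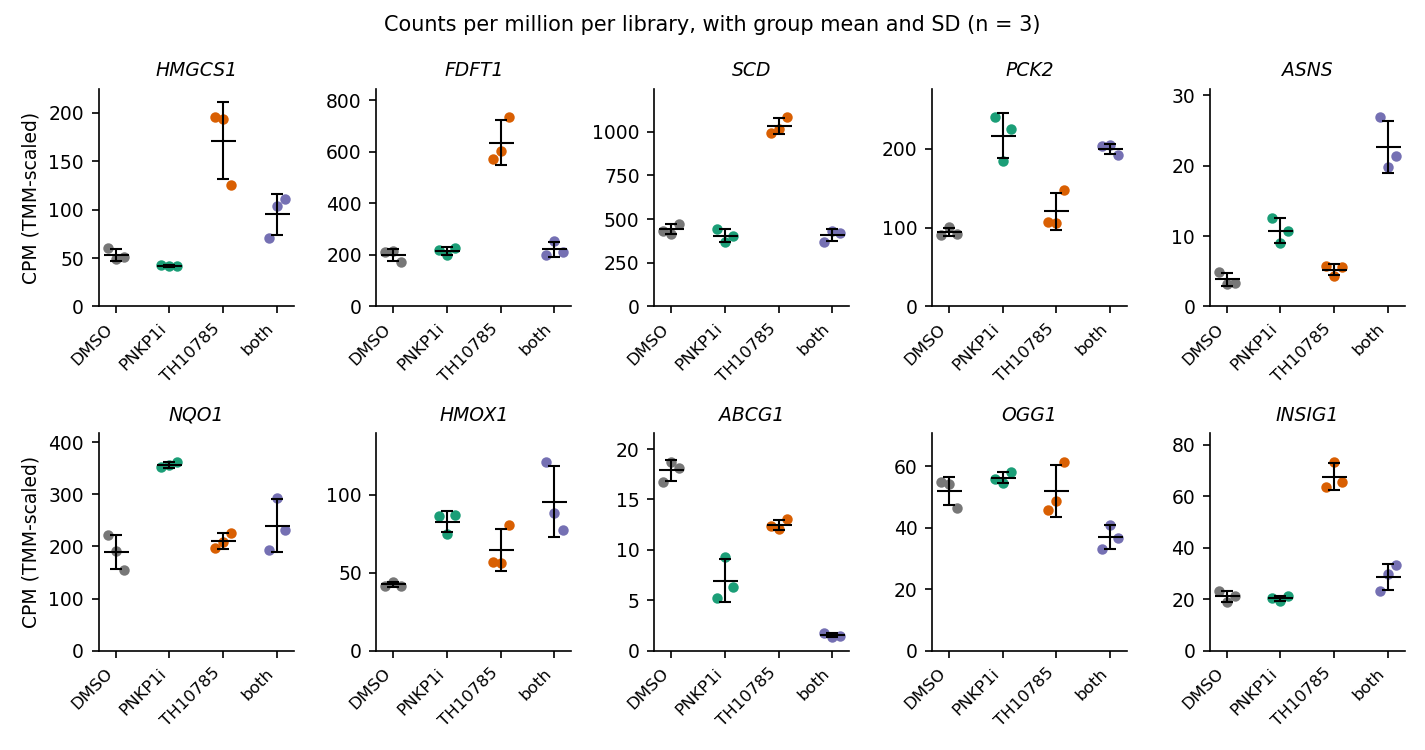
Expression of 10 genes in CPM (TMM-scaled, vertical axis), 1 point per library, with bars at the group mean and SD (n = 3). FDFT1 rose to 636 CPM with TH10785 and stood at 221 with both compounds, PCK2 was at 217 with PNKP1i and 200 with both, and ABCG1 was lowest with both, at 1.52.

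With both compounds the cells changed in 7093 genes, of which 3680 rose and 3413 fell, 1312 and 953 of them at least 2-fold. The genes of ATF4 rose nearly throughout: 34 of the 36 members of the ATF4 integrated stress response list rose and 0 fell (34 also when adjusted over the list alone), with a median of 1.09. ASNS rose 5.91-fold, from 3.84 ± 0.93 to 22.7 ± 3.7 CPM (log2 2.56, SE 0.21, adjusted p = 1.07e-06), DDIT4 by 1.54, CEBPG, a partner of ATF4, by 1.54 and PSAT1 by 1.48 on the log2 scale. The 13 genes encoded by the mitochondrial genome all fell, by a median of -1.39: COX2 went from 8600 ± 2200 to 2530 ± 510 CPM (log2 -1.77, SE 0.19, adjusted p = 7.5e-06), CYTB fell by 1.80, ATP6 by 1.59 and COX3 by 1.41. With the GC and length offsets described below, 34 of the ATF4 genes rose and 13 of the mitochondrial genes fell (median -1.69 for the latter). Mitochondrial genes held 2.51% to 3.19% of the counts in these libraries, 4.24% to 6.8% with DMSO, 3.88% to 3.92% with TH10785 and 4.65% to 5.13% with PNKP1i.

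The combination libraries had counts in 25184 to 26378 genes, against 23908 to 24256 with DMSO, 23311 to 24523 with TH10785 and 23764 to 24227 with PNKP1i. Their 10 highest genes held 4.97% to 5.16% of the counts, against 6.53% to 8.25% with DMSO. The combination libraries also differed from DMSO by base composition. Genes with a GC content under 40% lay 0.43 to 0.70 above the DMSO mean (median log2 CPM of 1219 genes, each of the 3 libraries), and genes over 60% lay between -0.41 and -0.38. TH10785 replicates 1 and 2 went the same way to a lesser degree, at 0.19 and 0.08 under 40% and -0.16 and -0.11 over 60%. TH10785 replicate 3 went the other way, at -0.66 and 0.26. The PNKP1i libraries did so to a lesser degree under 40%, at -0.29 to -0.10, and lay at -0.03 to 0.10 over 60%. The DMSO libraries lay at -0.06 to 0.07 under 40%. The genes that rose with the combination had a median GC content of 41.9% and those that fell 56.7%, against 49.3% for all tested genes. With per-library GC and length offsets, an alternative chosen after the trend was seen, 6039 genes were called, and 4182 (59%) of the 7093 kept their call and direction, 1992 as rises and 2190 as falls.

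**Figure D3:**
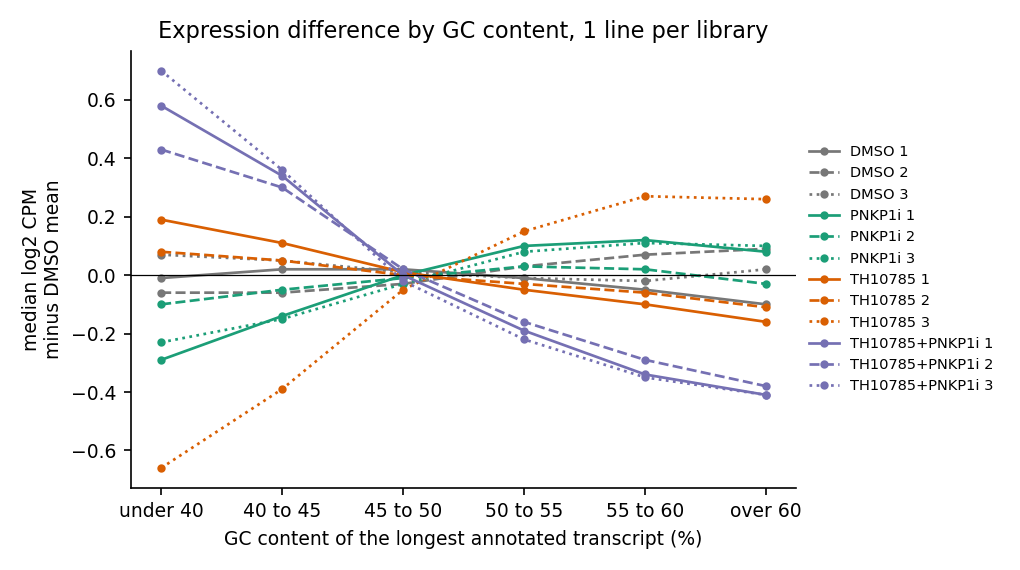
Median difference in log2 CPM from the DMSO mean (vertical axis) for genes in 6 bins of GC content of the longest annotated transcript (horizontal axis), 1 line per library coloured by group. The 3 combination libraries ran from 0.43 to 0.70 under 40% GC to between -0.41 and -0.38 over 60%, and TH10785 replicate 3 from -0.66 to 0.26.

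More genes of inflammation, early response and ribosomes rose than fell with the combination, in lists whose calls did not hold with an estimated correlation (adjusted p = 0.71 for ribosomal proteins and 0.579 for the others). In the NF-kB and inflammatory genes list 11 of 22 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.71. CXCL8, a neutrophil chemokine, rose 47-fold from 0.213 ± 0.093 to 10.3 ± 5 CPM (log2 5.55, SE 0.60, adjusted p = 7.24e-06). Its DMSO level lay near the 0.174 CPM that 3 counts make in those libraries, so the size of this fold is uncertain. TRAF1 rose by 1.81 and RELB, an NF-kB subunit, by 1.55. The 3 that fell were CCL2 (-2.13), BCL3 and LIF. In the immediate early genes list 13 of 24 rose and 3 fell (14 and 3 adjusted over the list alone), among them DUSP5, an ERK phosphatase (log2 2.39), MYC (1.12) and EGR1 (0.95). JUN, JUND and DUSP4 fell. Of the ribosome biogenesis and MYC targets 15 of 32 rose and 2, BOP1 and CAD, fell (15 and 3 adjusted over the list alone), with GNL3 at 1.24 and WDR43 at 1.33. Of the 73 cytosolic ribosomal proteins 26 rose and 1, RPS26, fell (26 and 0 adjusted over the list alone). With the offsets 16 and 2 of the NF-kB and inflammatory genes, 14 and 1 of the immediate early genes, 17 and 0 of the ribosome biogenesis genes and 28 and 3 of the ribosomal proteins rose and fell. CXCL8 was then at 4.68, GNL3 at 0.72 and WDR43 at 0.81.

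More genes of chromatin and cell division fell than rose with the combination, in lists whose calls did not hold with an estimated correlation (adjusted p = 0.579 for histones and 0.669 for G1/S and G2/M). Of the 30 replication-dependent histones 16 fell and 0 rose (17 fell adjusted over the list alone), with a median of -1.09. H2BC12 went from 499 ± 22 to 159 ± 36 CPM (log2 -1.65, SE 0.15, adjusted p = 2e-06), H4C9 fell by 1.68 and H2BC11 by 1.87, all members of families of near-identical genes whose single counts are uncertain. With the offsets 16 of the histones fell. In the G1/S and E2F target genes list 18 of 44 fell and 4 (DSCC1, RFC3, RFC4 and ORC6) rose, the same counts as adjusted over the list alone, with TK1 at -1.01 and RRM2, a subunit of ribonucleotide reductase, at -0.79. With GC and length offsets 20 of the G1/S and E2F target genes fell and 0 rose. In the G2/M genes list 18 of 40 fell and 2, CDK1 and MAD2L1, rose (the same adjusted over the list alone). PLK1, a mitotic kinase, went from 258 ± 24 to 113 ± 14 CPM (log2 -1.2, SE 0.15, adjusted p = 1.92e-05), KIF20A fell by 1.17 and GTSE1 by 1.01. With the offsets 24 of the G2/M genes fell and 0 rose.

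More genes of glycolysis, actin and matrix fell than rose, in lists whose calls did not hold with an estimated correlation (adjusted p = 0.609, 0.579 and 0.59). In the glycolysis list 13 of 20 fell and 3 rose (15 and 3 adjusted over the list alone). LDHA, the lactate dehydrogenase A subunit, fell from 1510 ± 100 to 746 ± 190 CPM (log2 -1.02, SE 0.16, adjusted p = 0.000141), while HK2, a hexokinase (1.25), SLC16A1, a lactate transporter (1.11), and LDHB rose. With GC and length offsets 8 of the glycolysis genes fell and 3 rose, and the list calls of glycolysis and of YAP and SRF targets ended (adjusted p = 0.0536 and 0.092). In the YAP/TEAD and SRF targets list 10 of 26 fell and 5 rose (13 and 5 adjusted over the list alone), with the contractile genes MYL9 at -1.79, CNN1 at -1.76 and ACTB, cytoplasmic actin, at -1.44. CCN1, CCN2, ANKRD1, TEAD1 and FHL2 rose. In the extracellular matrix and TGF-beta targets list 19 of 35 fell and 6 rose (20 and 9 adjusted over the list alone): COL3A1 went from 109 ± 9.4 to 15.7 ± 9 CPM (log2 -2.80, SE 0.32, adjusted p = 1.39e-05), TGFBI fell by 2.26 and COL1A1 by 1.27. With the offsets 9 of the YAP/TEAD and SRF targets fell and 5 rose, and 16 of the matrix genes fell and 7 rose, with COL1A1 at -0.83.

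These 12 lists were the ones camera called for the combination against DMSO, 5 up and 7 down. The adjusted p was 2.88e-16 for the ATF4 list, 8.87e-09 for the mitochondrial genes, 4.22e-07 for the histones, 0.000158 for ribosomal proteins, 0.00494 for NF-kB, G1/S and matrix genes, 0.006 for glycolysis, 0.00734 for immediate early genes, 0.00898 for G2/M, 0.0163 for YAP and SRF targets and 0.0209 for ribosome biogenesis. With an estimated correlation 0 lists were called, with adjusted p = 0.486 for ATF4, 0.579 for mitochondrial, histone, NF-kB, ribosome biogenesis, immediate early and YAP and SRF genes, 0.59 for matrix, 0.609 for glycolysis, 0.669 for G1/S and G2/M and 0.71 for ribosomal proteins. Fry, which does not compare a list with other genes, called 23 lists. Under the offsets the camera calls of glycolysis (adjusted p = 0.0536) and YAP and SRF targets (0.092) ended, and without DMSO replicate 1 that of ribosome biogenesis (0.0561).

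**Figure D4:**
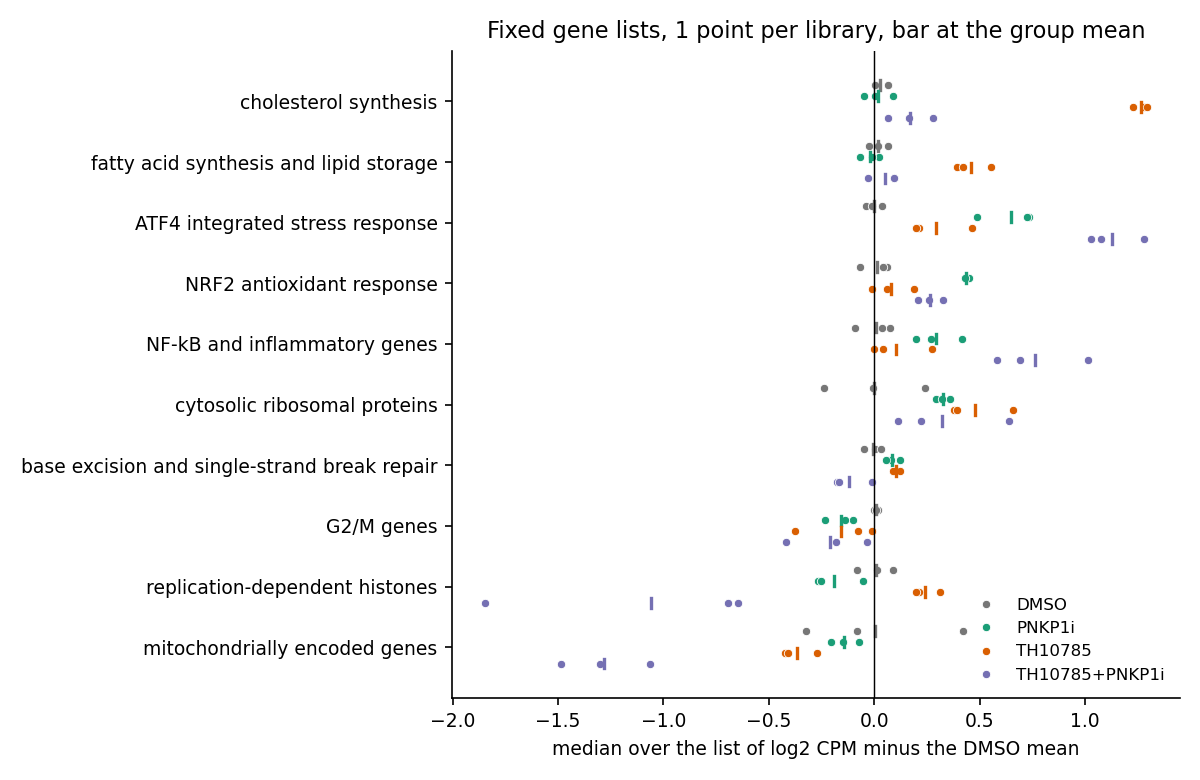
Median over each of 10 gene lists of the log2 CPM difference from the DMSO mean (horizontal axis), 1 point per library, with a bar at the mean of the 3 libraries of a group. The cholesterol synthesis list lay at 1.23 to 1.29 in the TH10785 libraries and at 0.06 to 0.28 with both compounds, the ATF4 list at 0.49 to 0.73 with PNKP1i and 1.03 to 1.28 with both.

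DNA repair genes went both ways with the combination. OGG1 (ENSG00000114026, chromosome 3, 9749944 to 9788219) fell from 51.8 ± 4.6 to 36.9 ± 3.9 CPM (SD, n = 3; log2 -0.49, SE 0.13, adjusted p = 0.00723, where the alternatives ran from 0.000964 to 0.0511, the last in the test against a fold change of 1.2). With the offsets OGG1 was at -0.33 (SE 0.12, adjusted p = 0.0316). In the base excision and single-strand break repair list 11 of 36 fell and 3 (APLF, TDP2 and POLD3) rose, the same counts as adjusted over the list alone, with LIG1, a DNA ligase, at -0.81 (adjusted p = 0.000216), POLD1 at -0.76, XRCC1 at -0.58 and APEX2 at -0.56. The list as a whole was not shifted (median -0.14, camera adjusted p = 0.267), and with the offsets 11 members fell and 6 rose, with LIG1 at -0.51, POLD1 at -0.29, XRCC1 at -0.27 and APEX2 at -0.36. Of the double-strand break and crosslink repair genes 18 of 38 rose, NBN by 1.21 and XRCC4 by 1.53, and 8 fell, RAD54L by 0.76 (19 and 8 adjusted over the list alone, camera adjusted p = 0.164). With the offsets 8 of the double-strand break and crosslink repair genes rose and 8 fell, with NBN at 0.57 and XRCC4 at 0.73. Of the nucleotide excision and mismatch repair genes 7 of 23 rose, GTF2H1 by 0.98, and 3 fell, DDB2 by 0.63 (the same adjusted over the list alone, camera adjusted p = 0.164), and with the offsets 3 rose and 2 fell, with GTF2H1 at 0.39.

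Damage and stress lists were mixed. Of the DNA damage checkpoint genes 7 of 25 rose and 7 fell (7 and 8 adjusted over the list alone): ATR, the replication stress kinase, rose by 1.18. H2AX (-1.32) and CDC25B (-0.93) fell. The median was 0.09 and camera's direction was down (adjusted p = 0.808), and with the offsets 4 of the DNA damage checkpoint genes rose and 7 fell (median -0.07), with ATR at 0.67 and CDC25B at -0.57. Of the p53 target genes 13 of 35 rose and 7 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.359). GDF15, a stress cytokine, rose from 13 ± 2.1 to 60.7 ± 24 CPM (log2 2.23, SE 0.23, adjusted p = 4.41e-06), PMAIP1, a BH3-only protein, by 1.55 and GADD45A by 1.11, and BTG2 fell by 0.82. With the offsets 10 of the p53 target genes rose and 7 fell, with PMAIP1 at 0.80 and GDF15 at 2.55. CDKN1A fell by 0.38 (adjusted p = 0.029) and MDM2 rose by 0.59 (adjusted p = 0.0223). Both of these calls ended with the offsets (-0.11, adjusted p = 0.312, and 0.22, adjusted p = 0.0893) and without DMSO replicate 1 or 2 or combination replicate 1 or 3 (CDKN1A 0.066, 0.0946, 0.0658 and 0.0942, and MDM2 0.0679, 0.0858, 0.06 and 0.0771). Over the alternatives the adjusted p ran from 0.00392 to 0.312 for CDKN1A and from 0.000272 to 0.0893 for MDM2. Of the NRF2 antioxidant response genes 14 of 34 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.126). SLC7A11, the cystine transporter, rose from 17 ± 2.4 to 92.6 ± 25 CPM (log2 2.45, adjusted p = 1.9e-06), TXNRD1 by 1.53, HMOX1 by 1.17 and GCLC by 1.14, and TKT, TALDO1, AKR1C1, AKR1C2, EPHX1 and KEAP1 were among those that fell. With the offsets 14 of the NRF2 antioxidant response genes rose and 9 fell, with SLC7A11 at 1.75 and HMOX1 at 1.40. CYP1A1 did not pass (0.74, adjusted p = 0.157).

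Most of the cholesterol response of TH10785 was missing from the combination. In the cholesterol synthesis list 10 of 24 rose and 2, LSS and SREBF2, fell (the same adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.151), and with the offsets 9 rose and 0 fell (median 0.25). CYP51A1, a sterol demethylase, rose by 0.92 and SQLE by 0.68 (0.47 and 0.59 with the offsets). FDFT1 was at 221 ± 28 CPM and SCD at 407 ± 33. In the fatty acid synthesis and lipid storage list 6 of 21 rose, ELOVL6 by 1.51, and 4 fell, SREBF1, the transcription factor of this program, by 1.11 and FADS2 by 0.78 (the same adjusted over the list alone, median 0.01, camera adjusted p = 0.763). With the offsets 6 rose and 5 fell in the fatty acid synthesis and lipid storage list, with SREBF1 at -0.65 and FADS2 at -0.41. Among called genes with a mean log2 CPM of at least 1 and groups that did not overlap, the largest rises with the combination were in OLAH, a thioesterase of fatty acid synthesis (log2 6.08, SE 0.56, adjusted p = 2.08e-06), the uncharacterised LOC644135 (5.87), CXCL8 (5.55), ESM1 (5.54), SPRR2D (5.25, from 0.248 ± 0.069 to 9.8 ± 11 CPM, one of a family of similar genes), OSCAR (5.14), MMP3, a matrix metalloproteinase (4.62), and SCG5 (4.56). The largest falls were in GALNT15 (-3.59), ABCG1 (-3.56, SE 0.22, adjusted p = 1.81e-07), MAB21L4 (-3.46), MYCN (-3.42), CXCL14 (-3.38), RNF43 (-3.23), SECTM1 (-3.12) and the non-coding H19 (-3.11). In 9275 genes (53.6%, where chance gives 10%) the 3 combination libraries did not overlap the DMSO libraries.

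The fold changes against DMSO were compared between treatments, across genes, which are not independent replicates. Of the genes raised by TH10785, 41 also rose with the combination (18.9 for independent lists) and of the 8 that fell all 8 did (1.58), while 5 went in opposite directions. The correlation was 0.36 and the covariance 0.113, where simulated unchanged groups sharing the DMSO libraries gave 0.51 and 0.0437. For PNKP1i, 25 rises (6.39 for independent lists) and 4 falls (0.79) were shared with the combination and 0 were opposite, with a correlation of 0.28 (0.52 simulated) and a covariance of 0.0816 (0.0436 simulated). TH10785 and PNKP1i shared 1 rise (0.154 for independent lists) and 0 falls, with a correlation of 0.55 (0.51 simulated) and a covariance of 0.0835 (0.0435 simulated). In the 20 simulations, where at most 4 genes were called in a comparison, the highest number of shared calls was 0 for each pair with the combination and 1 for TH10785 and PNKP1i. The 3 DMSO libraries were not split between the comparisons, so part of the excess of shared calls over independent lists may come from the shared controls.

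Against the single agents the combination was compared to see what each compound adds to the other. Against TH10785, 3918 genes rose and 3399 fell, and against PNKP1i 4226 rose and 3719 fell. The highest and lowest genes given here are among called genes with a mean log2 CPM of at least 1 and groups that did not overlap. OLAH rose by 4.86 against TH10785 and 4.55 against PNKP1i on the log2 scale, ESM1 by 4.32 and 4.24 and SPRR2D by 4.92 and 4.57, with KLHDC7B (4.73) also among the highest against TH10785. Against TH10785 the lowest were MAB21L4 (-4.25, SE 0.48, adjusted p = 1.94e-05), ALPP, placental alkaline phosphatase, which has close paralogs (-3.19), CLIC3 (-3.12) and ABCG1 (-3.04). Against PNKP1i they were CXCL14 (-3.21, SE 0.43, adjusted p = 8.56e-05), MYCN (-3.21), KRT14 (-3.12) and SECTM1 (-3.05). OGG1 was lower by -0.49 (SE 0.13, adjusted p = 0.00682) against TH10785 and -0.61 (adjusted p = 0.00154) against PNKP1i. With the offsets 53.7% of the calls against TH10785 and 49% of those against PNKP1i kept their direction and call.

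The interaction term asked whether the combination differed from the sum of the single effects. It passed in 5289 genes, 2855 above the sum and 2434 below it. The cholesterol synthesis list lay below: 14 of its 24 members were below and 0 above (15 below adjusted over the list alone), with a median of -1 (camera adjusted p = 1.58e-07, and adjusted p = 0.194 with an estimated correlation). In the fatty acid synthesis and lipid storage list 10 of 21 were below and 3 above (11 and 4 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0105, and 0.194 with an estimated correlation). Of the histones 15 of 30 were below and 0 above (median -1.21), of nuclear-encoded oxidative phosphorylation 26 of 58 (median -0.54), of ribosomal proteins 20 of 73 (-0.41), of glycolysis 14 of 20, with 2 above (-0.79), of the mitochondrial genes 7 of 13 (-0.71), of G1/S genes 17 of 44, with 7 above (-0.34), of antioxidant enzymes 12 of 29, with 2 above (-0.34), and of base excision and single-strand break repair 11 of 36, with 4 above (-0.27). Adjusted over the list alone 15 histone, 29 oxidative phosphorylation, 18 ribosomal protein, 15 glycolysis, 11 mitochondrial, 21 G1/S, 12 antioxidant and 14 repair genes were below. These 10 lists were the ones camera called for the interaction, all below the sum, and for the last 8 the adjusted p was 0.74 with an estimated correlation. Genes called above the sum had a median GC content of 40.9% and those below it 57.2%. With the offsets 38.2% of the interaction calls were kept, and the cholesterol synthesis median was -1.14. Values with the offsets are not given here for the other lists, so the GC trend may account for part of their shift. In the ATF4 list 10 of 36 were above and 2 below (the same adjusted over the list alone, median 0.24, camera adjusted p = 0.263).

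Among called genes with a symbol and a mean log2 CPM of at least 1, the interaction was highest for SPRR2D (log2 4.24, SE 1.57, adjusted p = 0.0498), ADGRL4 (3.56, SE 0.60, adjusted p = 0.00409), CLGN (3.34) and OLAH (3.33). It was lowest for MAB21L4 (-3.70, SE 0.63, adjusted p = 0.00424), KRT14 (-3.08), ALPP (-2.84) and SECTM1 (-2.72). OGG1 lay below the sum by -0.61 (SE 0.18, adjusted p = 0.0213). SPRR2D was called in 6 of the 22 settings, OLAH in 17 and OGG1 in 19. With the offsets the calls of SPRR2D and OLAH ended (adjusted p = 0.165 and 0.109), at a log2 interaction of 4.77 (SE 2.26) and 3.07 (SE 1.25). Among the settings where the call of OGG1 ended were those without DMSO replicate 3 (adjusted p = 0.0589) and without PNKP1i replicate 3 (0.0547). Over the 22 settings its log2 interaction ran from -0.73 to -0.49. The count of 5289 was 3154 with the offsets, of which 2018 (38.2% of the 5289) were kept calls, 3501 without DMSO replicate 3 and 3519 and 3492 without PNKP1i replicates 1 and 3.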

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

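The test of the interaction picked out the results of this part, and the predictions for the trend, scaling, library and cholesterol tests were written before those tests were run but after the main results were seen. Genes with a non-additive response numbered 5289, and 10 gene lists had a shifted interaction term, all of them downwards, of which 0 held with an estimated correlation. The log2 interaction was -0.61 for OGG1. It was 4.24 for SPRR2D, 3.56 for ADGRL4, 3.34 for CLGN and 3.33 for OLAH, and -3.70 for MAB21L4, -3.08 for KRT14, -2.84 for ALPP and -2.72 for SECTM1.

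The broad response to the combination could come from the GC trend of its libraries, which would leave at most 10% of the 7093 called genes once the trends are removed. The share that stayed called in the same direction was 59% (48.2% to 61.9% with a library left out), so the trend is unlikely to be the whole cause. It may account for part, since the median absolute log2 fold change of the 7093 called genes fell from 0.78 to 0.49 with the trends removed. The variance of the log2 fold changes of these genes fell by 27.9%. Their median SE also fell, from 0.19 to 0.15, so a smaller fold change could keep its call. Whether the trend arose in the cells or in library preparation was not tested. The prediction against that cause had named more than 0.5 of the genes, which the lowest of the leave-one-out values did not reach, and the comparison of these values with the 10% bound was chosen after they were seen. The interquartile range of the fold changes was 2.23 times that of PNKP1i (1.93 to 2.55 with a library left out). No scaling factor can change this range, so a scaling error is unlikely to be the source of the wider spread. Whether a scaling error is present cannot be told from it.

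Replicate 3 of TH10785 lay apart from its group, which may be due in part to its GC and length trend. Its distance from its partners fell from 0.54 to 0.34 once the trends were removed, under the 0.39 of combination replicate 1. The trends were fitted to these same libraries, so the distance could not rise. It stayed above the 0.26 and 0.21 of TH10785 replicates 1 and 2. A library of another group under its name is unlikely, since its cholesterol synthesis median was 1.29 where the highest of the 9 libraries of other groups was 0.28.

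Most of the rise of cholesterol synthesis genes with TH10785 was missing from the combination, where 10 of 24 rose (9 with the trends removed). A GC trend is an unlikely cause, because the median interaction of the list was -1.14 with the trends removed. TH10785 replicate 3 alone is also unlikely to be the cause, as the median was -0.94 without it. Whether PNKP1i blocks this response, or whether a general stress state of the cells does, could not be tested with these libraries.

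Group labels were also reassigned among the libraries. For the interaction, 1 of 100 splits, the real one, gave as many genes as 5289, with 3739 the highest other, so a chance assignment of all libraries is unlikely. The 1 other split that kept the combination libraries together gave that highest count, but a split that broke them up gave 3473. The splits therefore do not show that the count needs this group kept whole. They also do not separate non-additivity from a difference of this group alone. For each of the 5 comparisons of groups, 1 of 10 splits, the real one, gave as many genes as observed, and 0 was the highest other. For the lists, 2 of 10 splits gave as many as observed with TH10785 (highest other 10), 3 of 10 with PNKP1i (highest other 7) and 3 of 10 with the combination (highest other 12). With 10 splits a share under 0.05 cannot be reached, so the gene counts cannot be judged this way. For the lists, other splits gave as many as observed, as predicted for a chance assignment. The number of shifted lists is therefore not shown to exceed what reassigned labels give.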

How the results depend on the processing

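The GC and length offsets were chosen after the data were seen, and the other alternatives before the data were examined. The 97 genes of TH10785 became 338 with DESeq2, 513 with no low-count filter, 56 against a fold change of 1.2, 306 with the offsets and 44 to 178 with a library left out (44 and 47 without DMSO replicates 2 and 3, 53 without TH10785 replicate 2, 178 without combination replicate 1). The 34 of PNKP1i became 115 with DESeq2, 189 with no low-count filter, 1144 with only the groups compared, 12 against a fold change of 1.2, 91 with the offsets and 7 to 301 with a library left out (22, 13 and 8 without DMSO replicates 1, 2 and 3, 7 and 9 without PNKP1i replicates 1 and 3, 22 and 301 without TH10785 replicates 2 and 3, 67 without combination replicate 1). Both counts therefore depend on the method and on single libraries. For PNKP1i all 34 calls were kept without TH10785 replicate 3 and in the fit of only the groups compared (577 rises and 567 falls). That replicate is not part of this comparison, so it reaches the count only through what the 12-library model shares, such as the spread. The count of 34, with 88.2% rises, therefore holds for that shared model. The part played by the spread was not tested on its own. The 5289 interaction genes became 3154 with the offsets and 3492 to 6140 with a library left out (3501 without DMSO replicate 3, 3519 and 3492 without PNKP1i replicates 1 and 3). The counts for the combination against DMSO, TH10785 and PNKP1i stayed within a ratio of 1.5, though with the offsets 59%, 53.7% and 49% of the calls were kept, and 38.2% for the interaction.

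The shifted lists numbered 2 with an estimated correlation and 3 with fry for TH10785 (10 in the primary test), 1 and 2 for PNKP1i (7, and 7 to 12 with a library left out, 11 and 12 without combination replicates 1 and 3) and 0 and 23 for the combination (12). With the offsets 388, 561 and 846 of the calls for the combination against DMSO, TH10785 and PNKP1i and 289 of those for the interaction changed sign, and 9, 29, 65 and 3 were called in the opposite direction. Among the named genes signs turned only for genes that were not called. MDM2 with TH10785 ran from -0.07 to 0.36 (-0.07 without TH10785 replicate 1) and CYP1A1 with PNKP1i from -0.15 to 0.65 (-0.15 without PNKP1i replicate 3).

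With the replicate number as a block, 62 genes were called for TH10785 and 15 for PNKP1i, and the 10, 7 and 12 shifted lists did not change in number. Of 18 pairs of libraries with the same number in different groups, 1 had a correlation of residuals over 0.1, and 1 of 12 libraries was closest to its own number, so the numbers do not pair the libraries.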

Other observations

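Lists outside those called by camera were also mixed with the combination, and were chosen for this part after the results were seen. In the heat shock response list 10 of 22 members rose and 4 fell (12 and 4 adjusted over the list alone): HSP90AA1, a cytosolic chaperone, rose from 286 ± 9.9 to 717 ± 80 CPM (log2 1.33, adjusted p = 0.000607) and CHORDC1 by 1.11 (0.40 with GC and length offsets), while HSPB1 (-1.04) and CRYAB (-1.35), small heat shock proteins, fell. In the endoplasmic reticulum unfolded protein response list 11 of 25 rose and 5 fell (the same adjusted over the list alone). EDEM1 rose by 0.79, and MANF and CALR fell by 0.82 and 0.81. With the GC and length offsets 7 and 2 heat shock genes, and 5 and 6 unfolded protein response genes, rose and fell.

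Of the 10 epithelial cell markers 5 fell and 1 rose with the combination (the same adjusted over the list alone), with the keratins KRT17 at -1.87 (from 736 ± 47 to 202 ± 52 CPM), KRT5 at -2.96 and KRT14 at -2.78 (5 fell and 2 rose with the GC and length offsets). Of the 30 apoptosis regulators 12 rose and 6 fell (13 and 6 adjusted over the list alone), among them the BH3-only genes BMF (-2.16) and BCL2L11 (-1.03), which fell, and PMAIP1 (1.55, and 0.80 with the offsets), which rose. Of the 58 genes of nuclear-encoded oxidative phosphorylation 5 rose and 11 fell (4 and 9 adjusted over the list alone), with SDHA at -1.16, and with the GC and length offsets 1 rose and 13 fell. Of the 21 senescence secretory genes 7 rose and 10 fell (9 and 11 adjusted over the list alone), with a median of -0.38 (-0.11 with the offsets) and a mean of 0.52, which differ in sign. This mean takes a lower bound for 1 member without counts in DMSO.

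The medians of the ATF4 list per library were 0.49 to 0.73 with PNKP1i, 0.20 to 0.46 with TH10785 and 1.03 to 1.28 with both, and the list was not called for the interaction (camera adjusted p = 0.263). Protein levels, repair activity and cell numbers were not analysed here, so whether the fall of OGG1 changes repair is open.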
